A study of Mus musculus with 16 samples.

How the data were processed

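Genomic DNA from the tails of 8 C57BL/6 mice and of 1 male reference mouse was hybridised to 2-colour oligonucleotide arrays, 2 arrays per mouse with exchanged dyes. The array images were read with Agilent Feature Extraction 10.7.1.1 on a design with coordinates of mm9 (NCBI build 37), per the file headers. The deposited processed signals are intensities per spot and dye on a linear scale, background-subtracted, spatially detrended and scaled with a linear factor per dye, with no lowess step, per the file headers. The factors lay between 1.03 and 1.69 for green and between 0.656 and 1.31 for red. The deposited raw median signals are intensities of a spot and of its local background, without correction, per the file headers. The deposited log ratio of each spot is the log10 of red (Cy5) over green (Cy3), per the file headers, and was used only to check the processed signals: the largest difference per array lay between 0.0128 and 0.126.

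The series matrix holds the authors' log2 values, whose scale, centring and direction are not given in the sources used here. Set against the scanner values, each array's column had a slope of 1 where the reference was in Cy5 and of -1 where it was in Cy3, so that the values are log2 of reference over mouse, and the medians of the columns lay between -0.00744 and 0.0137. Of these values, 2661 were missing. The centring step stays unknown.

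Ratios were turned to mouse over reference by the dyes in the labels. The 6563 control spots and 107 to 689 spots per array flagged as outliers in either channel were left out. Each array was centred on its median over autosomal probes, with no loess or quantile step. Spots of the same probe were averaged (1030 probes were printed repeatedly), and the orientations of a mouse were averaged to 1 value. Median net signals per array were 563 to 896 in green and 717 to 1398 in red, and 289 to 2494 spots per array were not well above background.

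Regions were searched per mouse on autosomes broken at gaps over 1 Mb. The score of an interval was its summed log2 over probe noise times the square root of the number of probes. Probe noise was the robust SD of differences between neighbours, 0.0487 to 0.0613. The interval of highest score was taken recursively. A call needed a score of 6, 3 probes, a mean log2 of 0.25 in size, and 0.2 with the same sign in each orientation. Calls sharing a probe were merged into family regions, and a mouse carried a region where its calls of 1 sign covered at least 50% of the probes. Shares were tested with the exact two-sided binomial test against 50%, with exact Clopper-Pearson intervals at 95%. Intervals cover counting error only.

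Blocks were runs of at least 5 autosomal probes with gaps up to 10 kb: 2127 blocks of 154571 probes, with a median of 71 probes and 8692 bp. Block means were fitted with limma 3.58.1 (lmFit and eBayes, R 4.3.3) with sire, dam and offspring as separate coefficients, all 8 mice and Benjamini-Hochberg adjustment at 0.05. The spread came from the 6 offspring, with 5 residual degrees of freedom. The consensus correlation within slides was 0.0836. P-values measure the spread between littermates, which share their parents. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and numba 0.67.0.

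Both methods were tested on simulated data. With noise at the real probe positions (158318 probes) the search called 0 regions without planted shifts, and it recovered 200 of 200 planted regions of 3 to 20 probes and shifts of 0.3, 0.5, -0.5 or -1.0, with 0 false calls. Simulated noise was independent between probes, unlike the dye effects of the real arrays. For offspring against the reference (2127 blocks), limma recovered 200 of 200 shifted blocks with 10 false calls. For offspring against the parents it recovered 198 of 200 with 6 false calls. For sire against dam it recovered 193 of 200 with 4 false calls, and 44 of the 50 planted at a shift of 0.1. The planted shift was the same in all 6 offspring, or in the sire alone. These counts therefore do not hold for a variant that only some of the offspring carry.

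The tests, alternatives and the rule for named items were fixed before the data were examined. Named items were, per limma comparison, up to 25 past the threshold by size, per mouse the 5 calls of highest score, and up to 10 family regions each of those found in offspring alone and in all 8 mice, by score. The rule spoke of genes, but the files analysed pair no probe with a gene, and the gene table at hand is of another assembly (GRCm38.p6), so blocks and regions were named by mm9 coordinates and the planned gene lists were not run. Loci described as a whole, regions of 10 or more probes and carrier sets were chosen after their values were seen.

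Alternatives were the normexp background (offset 50, on median signals), the series matrix values, no filter on flagged spots, probes well above background on every array, each orientation alone, other thresholds, other block definitions, slide as a random block, parents as 1 group, robust empirical Bayes with an intensity trend, a log2 size of at least 0.25 and leaving out each offspring mouse. Chosen after seeing the data were at least 10 probes, leaving out the dam and offspring 4, 5 and 6, the X level or scan day in the fit, and mice of day 1 alone. GC content was not analysed here.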

Results

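Copy number along the autosomes was measured in the tail DNA of 8 C57BL/6 mice of 1 family: a sire, a dam and their 6 offspring. Array comparative genomic hybridisation, in which differently dyed DNA of a mouse and of a reference compete for the same probes, was run against 1 male reference mouse of the colony. Each mouse was hybridised on 2 arrays with the dyes exchanged, giving 16 arrays on 4 slides, each slide with 2 mice, scanned on 2 days. The 2 arrays of a mouse were counted as 1 sample, so that the sire group and the dam group each held 1 mouse and the offspring group held 6. The series title describes males exposed to gamma rays at 0.05 mGy per day for 400 days, whereas the design text lists the male of this family as not irradiated. No control family was analysed here, so no comparison of exposure was made. The array was a follow-up design with probes tiled densely around sites picked in an earlier screen of the same mice, so the counts are neither genome-wide nor independent of that screen.

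Each array carried 162432 measured spots for 158369 different probes, of which 158318 lay on autosomes, 48 on X and 3 on Y (mm9 coordinates). Of the different probes, 155152 were well above background in both channels on every array, and no measured spot was saturated. The scanner's log ratio noise between neighbouring probes lay between 0.117 and 0.140 per array. Values below are log2 of mouse over reference, the opposite direction to the values in the deposited series matrix. They are means of both dye orientations, with standard errors over the probes of a region, since each mouse was 1 sample. The number of arrays per mouse and of mice per group limits the precision.

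The search for regions asked where each mouse departed from the reference. It called 2188 regions over the 8 mice. The counts differed widely: 742 regions in offspring 4 and 643 in offspring 5, 290 in the dam, 266 in offspring 6 and 135 in offspring 1. There were 45 in offspring 3, 37 in the sire and 30 in offspring 2. Most calls were short gains. In offspring 4, 665 calls were gains and 699 spanned 3 or 4 probes, and the mice differed much less in regions of 10 or more probes, with 6 in offspring 4, 8 in the sire and 13 in the dam. No mouse had a replicate, so the counts were not tested between mice. Leaving out offspring 4 lowered the total to 1446 regions, and leaving out the dam and offspring 4, 5 and 6 lowered it to 247, a choice made after seeing the data.

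The same search on the difference between the dye orientations, in which copy number cancels, called 189 to 336 regions per mouse. That was more than the calls themselves in the sire, the dam and offspring 1, 2 and 3. The dye effect was shared between mice: arrays of different mice in the same orientation correlated with r from 0.53 to 0.85 over autosomal probes. The orientations of the same mouse, both turned to mouse over reference, correlated between -0.623 and -0.038 over the same probes. After removal of the dye effect shared with the other mice, a step chosen after seeing the data, the search on the dye difference called 4 to 25 regions per mouse and none of 10 or more probes.

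**Figure D1:**
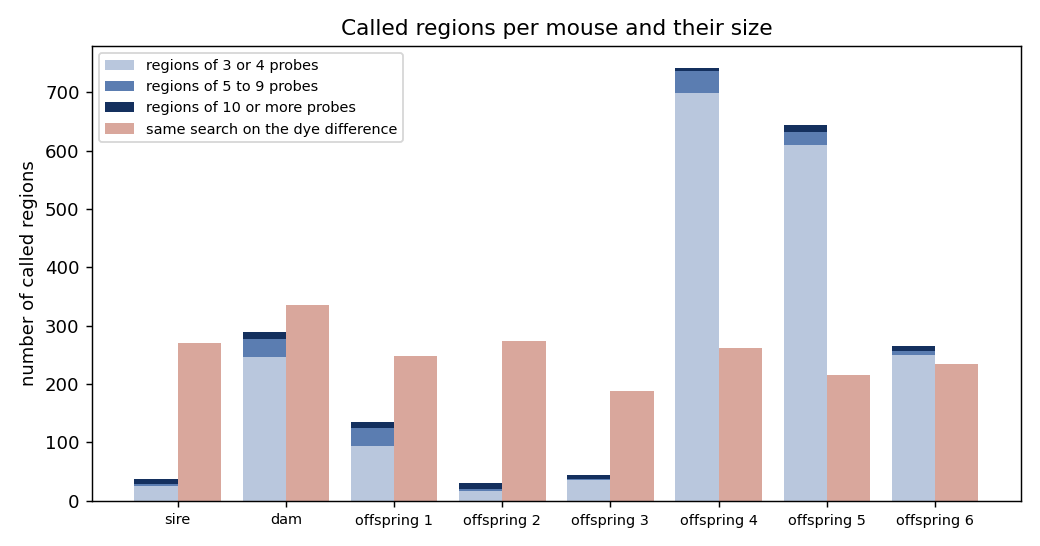
Number of called autosomal regions per mouse (vertical axis, bars from 0), stacked by the number of probes in a region, beside the number called on the dye difference of the same mouse. Offspring 4 and 5 had 742 and 643 regions, nearly all of 3 or 4 probes, and the sire had 37.

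In the sire, the male named in the family, 19 gains and 18 losses were called. The call with the highest score was a gain on chromosome 4 from 101109089 to 101270967, with a mean log2 of 0.39 over 1358 probes. The next was a loss on chromosome 16 from 24884801 to 24887347, with a log2 of -0.69 over 22 probes. The other 3 calls of the 5 highest lay on chromosome 14 between 53763769 and 54220024, with log2 values of -0.25 each. Calls of 10 or more probes numbered 8, of which 7 were losses and 6 of these lay at the chromosome 14 locus. With arrays of 1 orientation alone, 187 regions were called with the sire in Cy5 and 304 with the sire in Cy3, where dye effects do not cancel.

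The calls of all mice merged into 1061 family regions, of which 17 were carried by both parents, 16 by the sire alone, 265 by the dam alone and 763 by offspring only. Regions of 3 or 4 probes made up 916 of them (86.3%), and 21 held 10 or more probes.

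Carriage by all 8 mice asked where the whole family departed from the reference mouse in the same direction. This was the case at 2 family regions, both gains. Such a shared departure can also come from the reference mouse itself. The larger spanned 161997 bp of chromosome 4 from 101109089 to 101271085 and held 1360 probes. Its log2 was 0.39 ± 0.0049 in the sire, 0.71 ± 0.0075 in the dam, 0.34 in offspring 1, 2, 5 and 6, 0.67 ± 0.0084 in offspring 3 and 0.69 ± 0.0077 in offspring 4 (SE over probes). The mean of the offspring was 0.45 ± 0.18 (SD, n = 6). The smaller lay on chromosome 13 from 95705166 to 95707908 and held 5 probes, with log2 values from 0.17 to 0.29 and standard errors from 0.18 to 0.32. With at least 5 probes per call or the normexp background, 1 region was carried by all 8 mice. Leaving out offspring 4 gave 7 regions carried by all the remaining mice.

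A locus of 469893 bp on chromosome 14, from 53763769 to 54233661, was split by the search into 9 family regions, since its level lay close to the size required for a call. Over its 233 probes the log2 was -0.21 in the sire, -0.21 in the dam, -0.18 in offspring 1, -0.19 in offspring 2, -0.21 in offspring 3, -0.18 in offspring 5 and -0.19 in offspring 6, with standard errors from 0.0072 to 0.0097. In offspring 4 it was 0.0025 ± 0.0054. The interval was joined after seeing the calls.

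**Figure D2:**
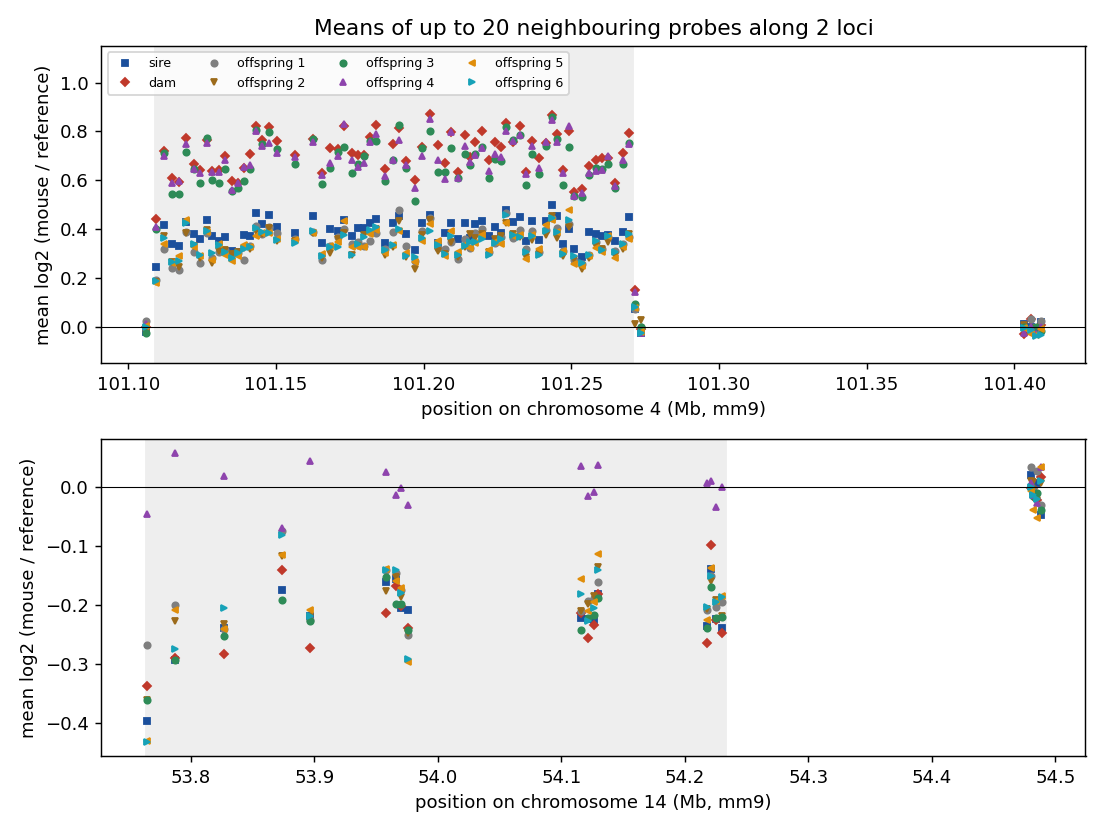
Mean log2 of mouse over reference (vertical axis) in windows of up to 20 neighbouring probes against position (Mb, mm9) on chromosomes 4 and 14, a symbol per mouse, with the loci shaded. On chromosome 4 the dam and offspring 3 and 4 lie near 0.7 and the other mice near 0.34, and on chromosome 14 offspring 4 stays near 0 while the other 7 mice lie below it.

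Transmission was examined at the regions carried by exactly 1 parent, where a heterozygous autosomal variant would reach 50% of offspring. The clearest region from the sire was the chromosome 16 loss, 2547 bp long, at -0.69 ± 0.057 in the sire and -0.04 ± 0.012 in the dam. All 6 offspring carried it, at -0.58 ± 0.063 (SD, n = 6). From the dam, a loss on chromosome 7 from 36989509 to 36991810 (19 probes) was at -0.65 ± 0.066 and was carried by offspring 2, 3, 5 and 6 at -0.52, -0.63, -0.46 and -0.51. Offspring 1 and 4 were at -0.04 and 0.03 there, and the sire at -0.0031. Of the 16 regions of the sire alone, 8 were in no offspring, and 17 of 96 pairs of an offspring and a region were carried (17.7%), against 529 of 1590 for the dam (33.3%). Of the 265 regions of the dam alone, offspring 4, 5 and 6 carried 152, 154 and 121, offspring 1 carried 82, offspring 3 carried 15 and offspring 2 carried 5.

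Over all such regions, 546 of 1686 pairs of an offspring and a region were carried, or 32.4% (exact 95% interval 30.1 to 34.7%, exact two-sided binomial p = 2.93e-48). The regions are linked and share carriers across chromosomes, so that p is too small. Exactly the dam and offspring 4, 5 and 6 carried 104 of them, on 18 autosomes, and exactly the dam and offspring 1 carried 73, on 19 autosomes. Carriers that recur on nearly every autosome are not those of separate heterozygous variants, so the share does not measure transmission. With the region of most probes per chromosome, where carriers also recur, 33 of 114 pairs were carried (28.9%, exact p = 8e-06). On arrays with the mouse in Cy5 alone that share was 52 of 114 (45.6%, exact p = 0.399) and did not pass. For the 10 regions of 10 or more probes, a limit set after seeing the data, the share was 22 of 60 or 36.7% (exact interval 24.6 to 50.1%, exact p = 0.0519), which did not pass the threshold of 0.05. Carriers recur here too: the dam and offspring 1 on chromosomes 1, 2, 10 and 11, and the dam and offspring 4, 5 and 6 on chromosomes 3 and 17. At the chromosome 14 region among the 10, the sire also had a shorter call, at -0.20. This share therefore does not measure transmission either.

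Among the regions of the dam alone, the largest was a loss of 40324 bp on chromosome 3 from 25416456 to 25456779, with 150 probes. It was at -1.83 ± 0.055 in the dam, -1.78 ± 0.056 in offspring 4 and -1.65 in offspring 5 and 6, with standard errors of 0.058 and 0.059. The sire and offspring 1 and 2 were within 0.0047 of 0, and offspring 3 was at -0.085 ± 0.0044. With 1 copy in place of 2 the log2 would be -1.0. Offspring 4, 5 and 6 lay below that while the sire stayed near 0, which argues against an autosomal loss inherited from the dam alone. A gain on chromosome 17 from 69736642 to 69737899 (17 probes) had the same carriers, at 0.48 in the dam and 0.45, 0.41 and 0.45 in offspring 4, 5 and 6, and lay between -0.02 and 0.01 in the other 4 mice. Exactly these 4 mice carried 104 family regions on 18 autosomes, 52 of them gains and 50 losses.

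The X and Y probes, which entered no autosomal call, were read beside these regions. The mean log2 of the 48 X probes was 0.88 ± 0.15 in the dam, 0.83 ± 0.19 in offspring 4, 0.75 ± 0.22 in offspring 5 and 0.74 ± 0.20 in offspring 6 (SD over probes). It was 0.0080 in the sire, -0.0080 in offspring 1, -0.0040 in offspring 2 and 0.0080 in offspring 3. The 3 Y probes were at -2.13 in the dam, -1.93, -1.45 and -1.53 in offspring 4, 5 and 6, and between -0.05 and 0.05 in the other mice. The SD over these probes was 1.99 in the dam and 1.84, 1.45 and 1.54 in offspring 4, 5 and 6. The Y probes thus differed widely from each other in these mice. The labels give the sex of the parents and of the reference but none for the offspring, and the planned comparisons did not group mice by these values.

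**Figure D3:**
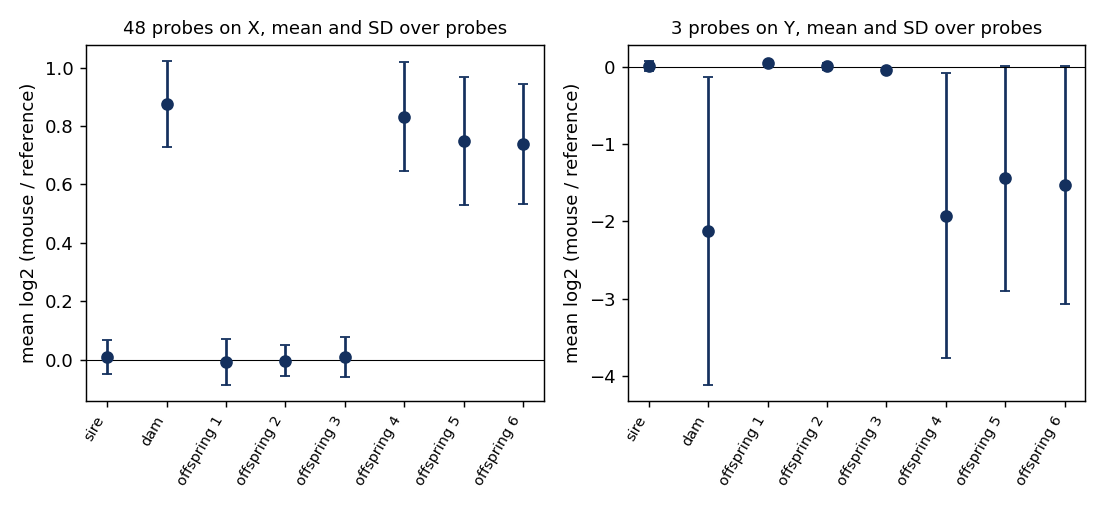
Mean log2 of mouse over reference (vertical axis) of the 48 X probes and the 3 Y probes in each mouse, with bars for the SD over probes. The dam and offspring 4, 5 and 6 lie between 0.74 and 0.88 on X, and the other 4 mice lie near 0.

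Regions carried by offspring and by neither parent were counted to find candidates that appeared in the offspring generation. There were 763 such regions, 682 gains and 80 losses, and 693 of them (90.8%) were carried by offspring 4 or 5. A single offspring carried 399, a pair carried 309 and 3 offspring carried 55. Both parents were within 0.1 of 0, with no overlapping call, at 171 regions. At the other regions a parent often lay part of the way. Of 10 or more probes there were 5, and at none of them were both parents within 0.1 of 0 without a call.

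The 10 of highest score were named. The only one of these carried by offspring 2 and 6 was a gain on chromosome 14 from 52008939 to 52021220 (11 probes), at 0.47 ± 0.075 in offspring 2 and 0.43 ± 0.11 in offspring 6, with 0.31 in the dam, which had a shorter call there, and 0.10 in the sire. The gain on chromosome 9 from 6222678 to 6224532 (11 probes) was at 0.47, 0.43 and 0.24 in offspring 4, 5 and 6, and at 0.21 in the dam and 0.085 in the sire, both of which had shorter calls there. The gain on chromosome 8 from 123010868 to 123010940 (3 probes) was at 0.84, 0.78 and 0.41 in these offspring, 0.23 in the dam and 0.12 in the sire. Offspring 4 and 5 shared gains on chromosome 2 from 169622889 to 169623127, on chromosome 7 from 60836574 to 60836812 and on chromosome 15 from 22902033 to 22902186, with means of 0.73, 0.54 and 0.64, where the dam was at 0.30, 0.23 and 0.13. Offspring 4, 5 and 6 shared gains on chromosome 7 from 37751558 to 37751727 (mean 0.56) and on chromosome 12 from 37262955 to 37263229 (mean 0.44), where the dam was at 0.26 and 0.34, and a loss on chromosome 14 from 109498095 to 109499404 (mean -0.31), where the dam was at 0.033. Standard errors over probes reached 0.57 at the chromosome 7 gain from 37751558 and 0.45 at the chromosome 2 gain. The gain called in offspring 1 alone, on chromosome 9 from 4130339 to 4132023, was at 0.32 ± 0.036 in offspring 1 but also at 0.27 ± 0.027 in the dam. In a new search with at least 5 probes per call the count of such regions was 272, and with a mean log2 of at least 0.4 it was 269. In the main search, such regions of 5 or more probes numbered 66.

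**Figure D4:**
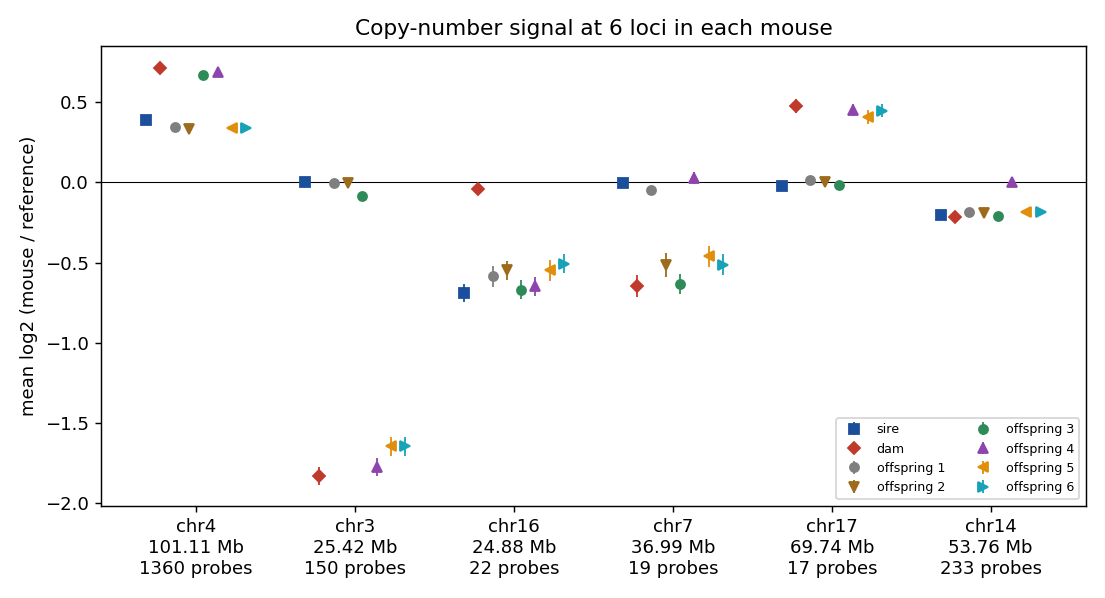
Mean log2 of mouse over reference (vertical axis) at 6 loci, a symbol per mouse, with bars for the standard error over probes; axis labels give chromosome, start in mm9 and number of probes. The loss on chromosome 16 is present in the sire and all 6 offspring, and the losses on chromosomes 3 and 7 in the dam and 3 or 4 offspring.

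Blocks of neighbouring probes were then compared between groups. Between the offspring and the reference, 11 of 2127 blocks differed, 3 higher and 8 lower (limma, adjusted p below 0.05). The lowest adjusted p belonged to the block on chromosome 16 from 24882524 to 24889276, at -0.19 ± 0.018 (SD, n = 6; adjusted p = 1.195e-07 by limma), lower in 6 of 6 offspring. The block on chromosome 4 from 101104835 to 101274369 was higher in 6 of 6, at 0.44 ± 0.17 (SD, n = 6; adjusted p = 0.00529 by limma). At the chromosome 14 locus 6 blocks were lower, with means from -0.32 to -0.14 and adjusted p from 0.0159 to 0.0452. Blocks on chromosome 9 from 40022399 to 40031907, on chromosome 8 from 78778218 to 78788788 and on chromosome 3 from 40624639 to 40637627 differed by only 0.026, 0.026 and -0.029. The last of these did not pass with the normexp background (adjusted p = 0.092). With slide as a random block 9 of the 11 passed, without the chromosome 3 block and the chromosome 14 block from 53890163. With the X level in the fit, chosen after seeing the data, 7 passed. That fit tests the offspring value at the X level of the reference, near which offspring 1, 2 and 3 lay. It does not test the mean of all 6 offspring, so the counts are not of the same quantity. The blocks on chromosomes 9, 8 and 3 and the chromosome 14 block from 53763769 lost their calls in that fit. The reference was 1 mouse, so its own spread is left out. Leaving out offspring 2, 3, 5 or 6 left 2 blocks, those on chromosomes 4 and 16. Leaving out offspring 1 gave 18 blocks and leaving out offspring 4 gave 9. With robust empirical Bayes and an intensity trend 30 blocks passed, of which 3 were shared with the 11: those on chromosomes 16, 8 and 9, but neither the block on chromosome 4 nor those on chromosome 14.

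Between the offspring and the mean of the parents, which autosomal inheritance would leave equal on average, 0 of 2127 blocks passed in limma, and 41 had an unadjusted p below 0.05. The lowest p was on chromosome 16 from 24882524, where the difference was -0.074 ± 0.013 (SE; adjusted p = 0.328 by limma). That block alone passed without offspring 6, and it alone passed with robust empirical Bayes and an intensity trend. Among mice scanned on day 1, a restriction to both parents and offspring 1 and 2 chosen after seeing the data, 4 blocks passed in limma with 1 residual degree of freedom, the blocks on chromosomes 4 and 16 among them. All mice of day 2 were offspring, so day 2 alone gives no value. All 6 offspring carried the sire's loss on chromosome 16, so their spread there was small (SD 0.0175) and left out the chance of transmission. At the chromosome 4 block the offspring split between levels, and the difference was -0.096 ± 0.098 (SE). Neither the 0 blocks nor the chromosome 16 block therefore measures change between generations. With scan day as a term in the fit, 0 blocks passed in limma, and 15 had an unadjusted p below 0.05.

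Between the sire and the dam, 1 block differed, with 20 at an unadjusted p below 0.05. The block on chromosome 16 from 24882524 to 24889276 differed by -0.19 ± 0.022 (SE; adjusted p = 0.0108 by limma), at -0.21 in the sire and -0.015 in the dam. Both parents lay on the same slide and day. Each was 1 mouse, assumed to vary like the offspring, so the p rests on the spread between littermates and not on replicates of a parent. The chromosome 4 block did not pass, with a difference of -0.31 ± 0.17 (SE; adjusted p = 1.00 by limma), because the offspring themselves fell on different levels there. On arrays with the mouse in Cy3 alone, 0 blocks passed in limma and 19 had an unadjusted p below 0.05, and among mice scanned on day 1 alone 4 blocks passed, those on chromosomes 4 and 16 among them.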

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

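The outlier test was set in advance, while the tests of inheritance and dimness below were chosen after the result was seen; the test of many-copy sequence was written before its value was seen. Of 43 values compared among the 6 offspring, 9 had a mouse whose gap to the nearest other was above Dixon's critical share of the range (0.625). Chance gives about 1 in 20, and the values on chromosome 14 belong to the same locus.

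Offspring 4 stood apart at 8 of them, all on chromosome 14. Its log2 was 0.0165 from 53763769 to 53958077 (nearest other -0.195), 0.0301 from 53973026 to 54116727 (nearest other -0.210) and -0.0016 from 54118526 to 54220098 (nearest other -0.197). In blocks of probes it was 0.0185 from 53817721, 0.0429 from 53890163, 0.0002 from 53950454, 0.0089 from 54113423 and -0.0050 from 54216632, with the nearest others between -0.209 and -0.163.

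Offspring 1 stood apart at the gain on chromosome 11 from 13153608 to 13154299, at 0.627 against 0.0654 in the nearest other. The region was compared because it ranked among the 5 top calls of offspring 1, so the chance of 1 in 20 does not apply to it. It is 1 of 73 gains carried by exactly the dam and offspring 1, with median log2 values of 0.36 and 0.46 there, 0.06 in the sire and -0.12 in offspring 6. Inheritance of separate autosomal variants is argued against, since the 73 gains lie on 19 autosomes, which assort independently. The probes were dimmer than uncalled probes of their blocks by a median log2 intensity of -1.38 (95% bootstrap interval -1.57 to -1.11). For sequence present in many copies brighter probes were predicted. Probes of different sequence were compared and GC content was not analysed, so the value does not decide on many-copy sequence. Dim probes may take part in these gains, and what sets the dam and offspring 1 apart stays open, with no biological explanation tested.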

How the results depend on the processing

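Of the alternative values of the main results, 115 stayed within 1.5 times the count or kept their side of the threshold, 41 moved further and 3 no longer passed. The series matrix and unfiltered spots moved none of them. The series matrix values are the same ratios up to sign and a shift per array, so they could hardly move a result. They add to the values that stayed, here and at named regions and blocks. Probes well above background on every array, a score of 8, gaps of 100 kb and slide as a random block also moved none. At the probe noise of every mouse, 3 probes at a mean log2 of 0.25 already score above 6. The score of 8 could therefore hardly move a result, and it left 30, 643 and 266 regions in offspring 2, 5 and 6, as before. Alternatives with at least 10 probes, without named mice, with the X level, with scan day or on day 1 alone were chosen after seeing the data. With at least 5 probes, a mean log2 of 0.4 and at least 10 probes, the total of regions was 823, 969 and 76, the regions of the sire 12, 14 and 8, those in offspring and in neither parent 272, 269 and 5, and those carried by all 8 mice 1, 1 and 1. The limit of 10 probes was applied to finished calls, so it removes shorter ones by construction. For the other limits the search was run anew, which can return longer or further intervals. Regions of 5 or more probes in offspring and in neither parent numbered 66 in the main search, against the 272. At a mean log2 of 0.4, offspring 2 had 63 regions, against 30 in the main search. Without the dam and offspring 4, 5 and 6 the total was 247. Calls were made per mouse, so totals without some mice are fixed by the counts per mouse. The normexp background gave 18 regions in the sire and 1 in all 8 mice. Arrays with the mouse in Cy5 or Cy3 alone gave 187 and 304 regions in the sire, 4 and 6 in all 8 mice, and 1678 and 1621 blocks between offspring and reference. In a single orientation the dye effect does not cancel, and gains were 29.7% of calls in Cy5 and 80.3% in Cy3 against 78.8%. The share of pairs carried over regions of at least 10 probes, where carriers also recur, was 36.7% (exact p = 0.0519). With 1 region per chromosome in Cy5 alone it was 45.6% (exact p = 0.399). Blocks between offspring and reference numbered 25 with parents as 1 group, 3716 of 157514 as single probes, 5 of 2017 with gaps up to 50 kb and at least 10 probes per block, 30 with robust empirical Bayes and an intensity trend (3 shared with the 11), 2 with a log2 size of at least 0.25 and 7 with the X level. Between offspring and mid-parent, the robust fit gave 1 block and day 1 alone 4. Between sire and dam, Cy3 alone gave 0, single probes 4, the size limit 0 and day 1 alone 4. Beyond what construction shows, the cause was not tested. Leaving out each offspring mouse gave totals of 1446 to 2158, offspring regions of 532 to 756, 2 to 7 regions in all remaining mice, transmission of 27.6 to 38.3% (21.1 to 32.6% with 1 region per chromosome), and 2 to 18, 0 to 1 and 1 to 1 blocks for the 3 comparisons. Of the alternative values at named regions and blocks, 65 stayed, 6 regions moved by more than the spread with normexp and 1 block lost its call. Signal over background limited 289 to 2494 spots per array, and probes above it on every array gave a total of 1931 regions. Sire and dam cannot be compared with the parents as 1 group. The gene lists, with a minimum of 10 probes per gene, were not run. No paired analysis was possible because all 6 offspring share the same 2 parents.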

Other observations

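All tests below were chosen after the result was seen, except that of dim probes.

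The levels of the chromosome 4 gain fell on 2 steps. The sire was at 0.39 and 4 offspring at 0.34, while the dam was at 0.71 and offspring 3 and 4 at 0.67 and 0.69. On a linear scale the excess of the dam over the reference was 2.05 times that of the sire. A hypothesis is that the sire carried 1 and the dam 2 extra units of the segment, of which each offspring received the dam's 1 and some the sire's. Every offspring then lies near a parental level, and the largest distance from the nearer parent was 0.056. That is consistent with the hypothesis, which was found and tested on the same data. A segment with 3 copies where the reference had 2 would give 0.58, above the 0.34 observed. The copy number of the reference mouse was not measured, so its 2 copies are an assumption and the units are relative to it.

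The chromosome 16 loss reached all 6 offspring. Loss on both copies in the sire is argued against, since the sire lost 1.14 times the share of signal that the offspring lost on average. If the sire had 1 copy, the chance of 6 of 6 offspring in either direction is an exact binomial p of 0.0312, at a locus picked after seeing it. The means of -0.69 in the sire and -0.67 to -0.51 in the offspring fall short of the -1.0 that 1 copy in place of 2 would give. The lowest of the 22 probes lay near that level, at -1.1 in the sire and between -1.16 and -0.98 in the offspring. How many other probes did was not counted.

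The 104 regions carried by exactly the dam and offspring 4, 5 and 6 were weighed against inheritance and the X and Y chromosomes. They lie on 18 autosomes, against variants inherited from the dam, since autosomes assort independently and the same 3 of 6 offspring recur on a further autosome with a chance of 1.56%. These 4 mice lay on 3 slides, 2 of which also held a mouse without the regions. A candidate explanation is sequence on X or Y that these probes also bind, since the lowest X level of the 4 mice was 0.737 and the highest of the others 0.008. On X and Y probes offspring 4, 5 and 6 read as the dam did and offspring 1, 2 and 3 as the sire did, so these calls follow sex. At the 50 losses the median log2 was -0.45 to -0.36 in the dam and offspring 4, 5 and 6, and -0.02 to 0.01 in the others. At the 52 gains the levels were graded: 0.42 and 0.40 in offspring 4 and 5, 0.29 in the dam and offspring 6, and 0.09 to 0.15 in the others. Losses and gains were both picked by these carriers, so a gap between the 4 mice and the others was built in. Within that limit, the split by sex was clean at the losses only. No sequence was compared, so which sequence the probes bind stays open.

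Gains called in offspring 4 (665, with a median length of 235 bp) had median levels of 0.33 in offspring 4, 0.29 in offspring 5, 0.16 in the dam and offspring 6, and 0.05 to 0.09 in the other mice. Probes at the background are argued against as the whole cause, since 597 gains were called on probes well above background on every array, but the normexp background lowered the gains to 436, so a contribution of background correction stays open. The test of the dose of X sequence could not decide: the dam reached 49.5% of the level of offspring 4 (bootstrap interval 47.3 to 51.4%), and these gains were picked in offspring 4. Offspring 5 and 6, on the same slide, had X levels of 0.75 and 0.74 but medians of 0.29 and 0.16 at these gains. That argues against X dose alone as what sets the level, while a contribution cannot be told apart from other sources. Dim probes may contribute, since they were dimmer than uncalled probes of their blocks by a median log2 intensity of -0.77 (interval -0.85 to -0.66). DNA quality was not tested, nor was any biological explanation.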
